A study of Mus musculus with 12 samples.

How the data were processed

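RNA from cultured mouse astrocytes was measured on 12 one-colour Affymetrix arrays, 3 for each combination of cell age (neonatal or adult) and brain section (wild-type or APdE9). Per the sample labels, samples were pooled (n = 3) before RNA isolation, so each array is taken to hold a pool. Per the submitters' protocol, cultures were shaken to remove microglia and their purity was checked by staining. Adult cells were isolated with Percoll and grown in DMEM/F12 with G5 supplement, and neonatal cells in DMEM without either, so medium and isolation cannot be told apart from age.

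Per the submitters' processing notes the signals were computed with RMA (no version given), and the deposited values of 8 arrays were taken as log2 signals. RMA output is usually log2, but the log base is not stated in the labels. In 45095 of 45095 complete probe sets the median over the 12 arrays was 0 within 1e-06, so each probe set had been centred and its level removed. In the deposited columns of the other 4 arrays the unit was recorded as a score, because 6 values there were whole numbers that seem to have lost their decimal point. These 6 values were set to missing and the rest of those columns was used as log2 values like the others. The direction of the signs was taken as deposited. Array medians lay between -0.039 and 0.034, and no level over background could be computed.

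Of 45101 probe sets, 64 controls were left out and 45037 tested. Of these, 34945 were paired with a single gene in the supplied annotation, 932 with several and 9160 with none, and 34741 of the single-gene probe sets matched the mouse RefSeq table, from which symbols were taken. The value of each of 18193 genes was the mean of its single-gene probe sets without damaged values where there were any. This rule was chosen after the data were seen, since the planned choice of the probe set with the highest mean needs levels. The planned filter on dim probe sets and the planned trend of variance on level were not run for the same reason. For some genes whose probe sets disagreed, the range is given.

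A linear model with 4 group means was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (with the data.table package, version 1.17.8), with moderated statistics (prior degrees of freedom 3.98, residual 8). It gave 6 comparisons: section in neonatal cells, section in adult cells, the difference of these, their mean, and age on each section. P-values were adjusted by Benjamini-Hochberg over probe sets, or over genes for named genes, with a threshold of 0.05. There were 49 gene lists, of which 837 of 916 gene entries were measured. The 48 lists with 3 or more measured genes were tested with camera at a preset correlation of 0.01 and adjusted over the lists of each comparison. Camera with an estimated correlation and fry were run beside it. The comparisons, gene lists, thresholds and rule for naming genes were chosen before the data were examined. For each comparison the rule named the 10 called genes with the largest rise and the 10 with the largest fall whose groups did not overlap, up to 4 called members of each list described, and a fixed panel of 16 genes. For the difference and the mean of the section effects a lack of overlap was not asked. Genes with only a RIKEN or predicted name were left out. Lists were described where their call held in each of the 12 fits that left out 1 array. Figures were drawn with matplotlib 3.10.9.

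The replicate numbers were checked as pairs by correlating deviations from the group means, with pairing taken to hold where each pair of a comparison passed 0.1. It held for section in neonatal cells (0.239, 0.183 and 0.477) and for age on APdE9 sections (0.460, 0.266 and 0.503), and a fit with the replicate number as a block called 1344 and 8944 probe sets there. Alternatives were quantile normalization, median centring, array weights, the replicate block, fitting only the arrays compared, robust variance estimates, another unit tested, a filter on SD that dropped 40% of probe sets, other thresholds, restored decimal points and leaving out each array. On simulated data with 45037 probe sets, a log2 change of 1 was recovered for 82.1% of changed probe sets in the neonatal comparison, 80.6% in the adult one, 50.7% in their difference and 97.0% in their mean. The shares were 83.6% for age on wild-type sections and 76.1% for age on APdE9 sections. At a log2 change of 0.5 they were 8.96%, 17.9%, 1.49%, 41.8%, 16.4% and 16.4% in the same order. The simulation changed few probe sets (132 calls in the neonatal comparison, against 901 in the data). It drew noise independently for each array, with no effect of the replicate number. The shares thus do not give the sensitivity of the real comparisons. Some genes of the panel and lists are not reported here, and raw array images were not used here.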

Results

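Transcripts were measured on 12 one-colour Affymetrix mouse arrays, each hybridised with RNA from cultured astrocytes that carried green fluorescent protein (eGFP). The astrocytes came from neonatal mice (3 d per the sample labels, although the protocol text gives 2 days) or from adult mice of 6 to 8 weeks, and were kept for 22 h on a brain section. The section came from a wild-type mouse or from a transgenic APdE9 littermate, which carries a chimeric mouse and human amyloid precursor protein gene with the Swedish mutation under the prion protein promoter. The fluorescent cells were then detached with trypsin and picked from the section by suction. There were 3 arrays for each of the 4 combinations of age and section. The labels call the arrays biological replicates and say that samples were pooled before RNA isolation, so the p-values measure only the spread between these pools, which may be partly technical. The table holds 45101 probe sets, of which 45037 were tested after leaving out 64 controls. Each value is a log2 signal from which the median of that probe set over the 12 arrays had been removed, so differences between groups can be read but levels cannot. The number of arrays limits the precision.

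The age of the astrocytes separated the arrays more than the section did. The first principal component took 59.9% of the variance and separated adult from neonatal cells, and the second took 13.9% and separated the adult cells on APdE9 sections from those on wild-type sections. Principal component 3 took 8.16% and separated the arrays numbered 3 from those numbered 1 in all 4 groups. Within groups, arrays correlated between 0.515 and 0.844 over the centred values, lowest between a pair of neonatal arrays on wild-type sections. One array stood apart from the rest: neonatal wild-type replicate 2 lay between the other 2 arrays of its group for 47.3% of the probe sets, where chance gives 33.3%, against 24.4% to 39.2% for the other 11 arrays.

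**Figure D1:**
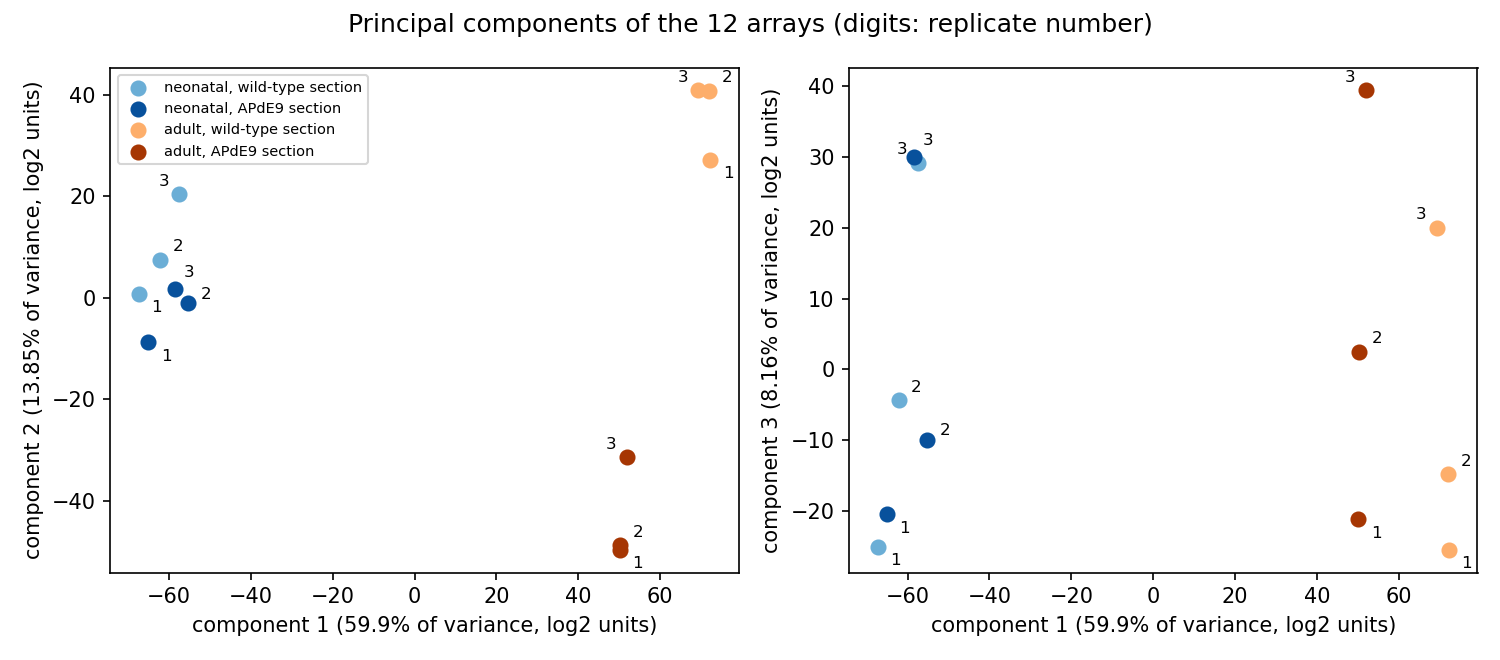
Each point is 1 of the 12 arrays, placed by its score in log2 units on the first and second principal components (left) and on components 1 and 3 (right), with colour for age and section and a digit for the replicate number. Adult and neonatal arrays lie on opposite sides of the first component (59.9% of variance), the 2 adult groups lie apart on the second (13.85%), and the arrays numbered 3 lie above the arrays numbered 1 on component 3 (8.16%).

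The first comparison asked what an amyloid-bearing section did to neonatal astrocytes, set against a wild-type section. Cholesterol biosynthesis genes fell in 14 of 19 cases with none higher. Among them Idi1, an isopentenyl-diphosphate isomerase, was lower by a log2 difference of -1.40 ± 0.25 (SE of the limma fit, n = 3 arrays per group; adjusted p = 0.00991), and Cyp51, lanosterol demethylase, by -1.18 ± 0.21 (adjusted p = 0.00938). Of 19 astrocyte markers 8 fell and none rose. Aldoc, a brain aldolase, was at -1.05 ± 0.08 (adjusted p = 3.7e-05), Gfap, the intermediate filament protein of astrocytes, at -1.02 ± 0.11 (adjusted p = 0.000608), and Aqp4, the water channel of astrocyte endfeet, at -0.74 ± 0.08 (adjusted p = 0.000516). Adjusted over the list alone, 17 cholesterol genes and 14 astrocyte markers were lower. With camera the cholesterol list had an adjusted p of 1.1e-22 (adjusted p = 0.0961 with an estimated correlation) and the astrocyte list 1.04e-14 (adjusted p = 0.00878 with an estimated correlation). The adjusted p of Idi1 became 0.057 without neonatal wild-type replicate 2 and 0.058 with only the 6 arrays compared.

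Of 21 microglia markers 4 rose in the neonatal cells on APdE9 sections and none fell, and 8 were higher when adjusted over the list alone. These were Ly86 (log2 difference 1.11 ± 0.20, limma adjusted p = 0.00961), Selplg (0.90 ± 0.22, adjusted p = 0.0389), the calcium-binding microglial protein Aif1 (0.87 ± 0.20, adjusted p = 0.0334) and the lysosomal glycoprotein Cd68 (0.83 ± 0.18, adjusted p = 0.0246). The list had a camera adjusted p of 4.35e-08 (adjusted p = 0.259 with an estimated correlation, and 0.0532 with the directional fry test). Each of these 4 calls was lost on leaving out single arrays. Without neonatal wild-type replicate 2 the adjusted p was 0.057 for Ly86, 0.15 for Selplg, 0.163 for Aif1 and 0.115 for Cd68. For Selplg, Aif1 and Cd68 it was 0.126, 0.0993 and 0.0863 without neonatal wild-type replicate 3, and 0.138, 0.131 and 0.0741 without neonatal APdE9 replicate 1. It was 0.0732, 0.0671 and 0.0788 for the same genes without neonatal APdE9 replicate 2, and 0.0941, 0.0613 and 0.0655 without neonatal APdE9 replicate 3. Without adult APdE9 replicate 2 it was 0.06 for Selplg and 0.0514 for Aif1, and without adult wild-type replicate 2 it was 0.0605 for Selplg. With only the 6 arrays compared it was 0.0695 for Aif1 and 0.056 for Cd68, and with the 8 arrays numbered 1 and 2 it was 0.095 for Ly86, 0.0788 for Selplg, 0.2 for Aif1 and 0.095 for Cd68. The arrays do not tell higher levels of microglia genes in astrocytes from a larger share of microglia among the picked neonatal cells. Whether that share differed between the sections, and what it adds to the lower astrocyte markers, was not tested.

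Interferon response genes rose in 4 of 26 cases with none lower, and cell cycle genes fell in 5 of 31 cases with none higher. Ifit2 was higher by 0.76 ± 0.12 (limma adjusted p = 0.00512) and the antiviral GTPase Mx1 by 1.22 ± 0.26 (adjusted p = 0.0215). Plk1, a mitotic kinase, was lower at -1.29 ± 0.24 (adjusted p = 0.0105) and Cdc20, an activator of the anaphase-promoting complex, at -1.15 ± 0.23 (adjusted p = 0.0169). Adjusted over the list alone, 8 interferon genes were higher and 17 cell cycle genes lower. With camera the adjusted p was 2.7e-06 for the interferon list (adjusted p = 0.4 with an estimated correlation) and 1.46e-05 for the cell cycle list (adjusted p = 0.519 with an estimated correlation). The directional fry test called neither (0.155 and 0.17). Mx1 lost its call without neonatal wild-type replicate 2 (adjusted p = 0.0966) or 3 (0.05) and without neonatal APdE9 replicate 1 (0.09) or 3 (0.0757). Cdc20 lost it without neonatal wild-type replicate 2 (0.0632) and without neonatal APdE9 replicate 1 (0.0569) or 2 (0.0652). With the 8 arrays numbered 1 and 2 the adjusted p was 0.178 for Mx1 and 0.0633 for Plk1.

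Among pan-reactive astrocyte genes 4 of 13 fell, led by the protease inhibitor Serpina3n (-1.21 ± 0.12, limma adjusted p = 0.000278) and Gfap, and 1 rose. The list's camera adjusted p was 0.00919 (adjusted p = 0.259 with an estimated correlation), and 1 gene was higher and 4 lower when adjusted over the list alone. Of 15 glutamate and ion homeostasis genes, which include Aqp4, 4 fell and 10 were lower over the list alone (camera adjusted p = 6.11e-08; adjusted p = 0.188 with an estimated correlation). Of 30 extracellular matrix genes 5 fell and 1 rose, and 10 were lower and 1 higher over the list alone (camera adjusted p = 0.000818; adjusted p = 0.4 with an estimated correlation, and 0.0754 with fry). Of 12 ependymal and choroid plexus markers 3 fell and 6 were lower over the list alone (camera adjusted p = 0.00386; adjusted p = 0.283 with an estimated correlation, and 0.0557 with fry). Of 9 genes of the A1-type reactive set 2 rose and 4 were higher over the list alone (camera adjusted p = 0.00714; adjusted p = 0.188 with an estimated correlation). These 10 of the 15 called lists kept their call in each of the 12 fits that left out 1 array. Neuron and oligodendrocyte markers were not called, with median log2 differences of -0.04 for each.

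The 10 genes with the largest rise in neonatal cells were Slfn4 (2.25 ± 0.24), the chemokine gene Ccl12 (2.13 ± 0.28), the myelin basic protein gene Mbp (1.80 ± 0.20), the cysteine protease inhibitor gene Cst7 (1.76 ± 0.20), the efflux transporter gene Abcb1a (1.70 ± 0.21), Gatm of creatine synthesis (1.66 ± 0.20), the cytokine gene Il33 (1.64 ± 0.13), Cd300lf (1.51 ± 0.23), the interleukin 7 receptor gene Il7r (1.30 ± 0.14) and Themis2 (1.26 ± 0.24). The 8 probe sets of Mbp disagreed, from -0.06 to 3.75. The 10 with the largest fall were Nnat (-1.59 ± 0.11), the urea transporter gene Slc14a1 (-1.58 ± 0.11), Cdsn (-1.49 ± 0.13), Psd2 (-1.47 ± 0.19), the ciliary gene Rsph4a (-1.46 ± 0.20), Itih3 (-1.43 ± 0.09), Idi1, Elobl (-1.37 ± 0.21), the Wnt inhibitor gene Wif1 (-1.37 ± 0.17) and the Wnt ligand gene Wnt5b (-1.36 ± 0.10). The limma adjusted p of these 20 genes lay between 2.5e-05 and 0.0119. Without neonatal wild-type replicate 2 it was 0.0662 for Themis2 and 0.057 for Idi1, and with only the 6 arrays compared 0.0666 and 0.058. That of Themis2 was 0.0602 with the 8 arrays numbered 1 and 2. Of the fixed panel, Aldh1l1, a folate enzyme of astrocytes, fell by 0.50 (SE 0.08, adjusted p = 0.00542, and 0.101 with the 8 arrays numbered 1 and 2). The glutamate transporter gene Slc1a3 was at -0.37 ± 0.09 (adjusted p = 0.054, and 0.0286 with the replicate number as a block), Gja1 at -0.31 (adjusted p = 0.0695), Prnp at -0.34 (0.0726), Apoe at -0.26 (0.183), App at -0.08 (0.786), Clu at -0.12 (0.697), S100b at 0.24 (0.377), Nes at 0.17 (0.841), Slc1a2 at -0.06 (0.901) and Vim at -0.04 (0.911). With array weights Slc1a3 (0.0114), Prnp (0.0133) and Gja1 (0.0146) passed, as did Slc1a3 with median centring (0.0473) and Gja1 with quantile normalization (0.0417).

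In all, 901 of 45037 probe sets passed a Benjamini-Hochberg adjusted p of 0.05 in neonatal cells, 262 higher and 639 lower, from 220 higher and 464 lower genes. The count fell to 289 without neonatal wild-type replicate 2, 514 without neonatal wild-type replicate 3, 485 without neonatal APdE9 replicate 1 and 516 without neonatal APdE9 replicate 2. It was 294 when only the 6 arrays compared were fitted and 2250 with array weights.

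The second comparison put adult astrocytes on the same pair of sections. Interferon response genes rose in 21 of 26 cases with none lower. Irf7, a transcription factor that drives type I interferon genes, was higher by a log2 difference of 3.06 ± 0.17 (SE of the limma fit, n = 3 arrays per group; adjusted p = 2.22e-07) and Bst2, which tethers enveloped viruses to the cell, by 2.01 ± 0.18 (adjusted p = 1.31e-05). Of 17 antigen presentation genes 7 rose and none fell, led by the class I genes H2-K1 (1.37 ± 0.08, adjusted p = 2.9e-07) and H2-D1 (0.76 ± 0.07, adjusted p = 1.64e-05). The list counts adjusted over the list alone were 21 and 9 higher. Camera gave an adjusted p of 4.4e-14 for the interferon list (adjusted p = 0.254 with an estimated correlation) and 5.01e-05 for antigen presentation (adjusted p = 0.0598 with an estimated correlation).

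Cell cycle genes fell in 25 of 31 cases and cholesterol biosynthesis genes in 18 of 19 in adult cells, with none higher in either list. Mki67, the proliferation marker, was at -2.46 ± 0.20 (limma adjusted p = 5.98e-06) and cyclin A2, Ccna2, at -2.19 ± 0.26 (adjusted p = 0.000117). Hmgcs1, the hydroxymethylglutaryl-CoA synthase of the mevalonate pathway, was at -1.68 ± 0.17 (adjusted p = 2.36e-05) and Idi1 at -1.55 ± 0.25 (adjusted p = 0.00109). Adjusted over the list alone, 25 cell cycle genes and 19 cholesterol genes were lower. Camera gave an adjusted p of 2.38e-19 for cell cycle (adjusted p = 0.262 with an estimated correlation) and 2.13e-16 for cholesterol synthesis (adjusted p = 0.119 with an estimated correlation). Among 30 extracellular matrix genes 16 fell and 5 rose, and 20 were lower and 5 higher over the list alone (camera adjusted p = 2.74e-05; adjusted p = 0.312 with an estimated correlation). Thrombospondin 1, Thbs1, was at -2.28 ± 0.47, tenascin C, Tnc, at -1.97 ± 0.40 and the type I collagen gene Col1a1 at -1.79 ± 0.16.

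Lipoprotein and lipid transport genes rose in 7 of 14 cases with none lower, and 11 were higher over the list alone. Apoe, the main lipid carrier made by astrocytes, was at 1.92 ± 0.09 (limma adjusted p = 1.05e-07) and Apod at 1.36 ± 0.15 (adjusted p = 6.71e-05). For this list the camera adjusted p was 0.000136 (adjusted p = 0.104 with an estimated correlation). Of 17 oxidative stress response genes 7 rose and 1 fell, and 8 were higher and 1 lower over the list alone (camera adjusted p = 0.00256; adjusted p = 0.104 with an estimated correlation). The glutathione transferase Gsta4 was at 1.84 ± 0.12 and Gclm, a subunit of the enzyme that begins glutathione synthesis, at 1.59 ± 0.11. Of 23 unfolded protein response genes 4 fell, led by Chac1 (-1.51 ± 0.13) and asparagine synthetase, Asns (-1.16 ± 0.11), and the same number were lower over the list alone (camera adjusted p = 0.00497; adjusted p = 0.309 with an estimated correlation). Of 22 glycolysis and hypoxia genes 6 fell and 1 rose, and 7 were lower and 2 higher over the list alone (camera adjusted p = 0.0035; adjusted p = 0.493 with an estimated correlation). The vasodilator peptide gene Adm was at -2.11 ± 0.25 and Pdk1, a kinase that restrains pyruvate dehydrogenase, at -0.85 ± 0.17.

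Immediate early genes fell in 8 of 23 cases with none higher, the same 8 in number over the list alone (camera adjusted p = 2.74e-05; adjusted p = 0.424 with an estimated correlation). Among them Nr4a1 was at -1.85 ± 0.47 (limma adjusted p = 0.0172), Fosb at -1.78 ± 0.41 (0.0101) and Btg2 at -1.72 ± 0.25 (0.000514). Without adult wild-type replicate 2 the adjusted p was 0.0812 for Nr4a1 and 0.0515 for Fosb, and without adult APdE9 replicate 3 it was 0.0567 for Nr4a1.

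Of 21 microglia markers 7 rose in adult cells on APdE9 sections and 1 fell, with the same counts over the list alone. The lysosomal protease gene Ctss was at 3.53 ± 0.22 (limma adjusted p = 7.5e-07), Cd68 at 1.72 ± 0.18 (3.71e-05), the complement gene C1qc at 1.01 ± 0.21 (0.00584) and Tmem119, a marker of resident microglia, at -0.85 ± 0.13 (0.000545). Of 18 plaque-associated microglia genes 6 rose and 1 fell, with 7 higher and 2 lower over the list alone, led by Apoe and by galectin 3, Lgals3 (1.28 ± 0.12). The camera adjusted p was 0.00315 for microglia markers (adjusted p = 0.424 with an estimated correlation) and 0.0152 for the plaque-associated list (adjusted p = 0.424 with an estimated correlation). With quantile normalization over the 12 arrays they were 0.151 and 0.0782, and that of C1qc was 0.775. Neuron and oligodendrocyte markers were not called in adult cells, with medians of -0.05 and 0.12.

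The 10 genes with the largest rise in adult cells were the chemokine gene Ccl5 (4.97 ± 0.08), the collagenase gene Mmp13 (4.29 ± 0.48), Ctss, Ifi207 of the interferon-inducible p200 family (3.33 ± 0.45), the macrophage elastase gene Mmp12 (3.13 ± 0.13), the B-cell coactivator gene Pou2af1 (3.10 ± 0.15), Irf7, the acute phase gene Saa3 (2.97 ± 0.26), the siderophore-binding lipocalin gene Lcn2 (2.83 ± 0.14) and the aldehyde dehydrogenase gene Aldh3a1 (2.77 ± 0.11). The 10 with the largest fall were the neutrophil-attracting chemokine genes Ppbp (-5.66 ± 0.23) and Cxcl5 (-4.43 ± 0.19), Elobl (-3.80 ± 0.21), the caveolar gene Cavin2 (-3.68 ± 0.13), the smooth muscle genes Actg2 (-3.60 ± 0.21), Tagln (-3.37 ± 0.15) and Myl9 (-2.94 ± 0.15), Ms4a4d (-3.05 ± 0.25), Klf2 (-2.80 ± 0.24) and Lrrc15 (-2.77 ± 0.13). The limma adjusted p of these 20 genes lay between 3.09e-12 and 0.000263. Of the fixed panel, S100b rose (0.61 ± 0.12, adjusted p = 0.00309), as did Aqp4 (0.58 ± 0.08, 0.000298), and Gja1, the main astrocyte connexin, fell (-0.56 ± 0.09, 0.000657). Clu (0.42 ± 0.10, 0.0122), Slc1a3 (0.31 ± 0.09, 0.0406) and App (-0.31 ± 0.08, 0.0222) passed the test, but without adult APdE9 replicate 2 their adjusted p was 0.059, 0.11 and 0.0504. Slc1a3 also lost its call without adult APdE9 replicate 1 (0.107) or 3 (0.0585), without adult wild-type replicate 1 (0.0898), 2 (0.0727) or 3 (0.118), and without neonatal wild-type replicate 2 (0.0587). The adjusted p of App was 0.0883 without adult wild-type replicate 1 and 0.0706 without adult APdE9 replicate 1. With the 8 arrays numbered 1 and 2 it was 0.115 for App and 0.151 for Slc1a3. Their probe sets went both ways, from -0.92 to 0.11 for App and -0.26 to 0.88 for Slc1a3. With quantile normalization the adjusted p of Clu was 0.674 and that of Slc1a3 was 0.543, and that of Slc1a3 was 0.0516 with median centring and 0.177 with its most variable probe set. Gfap (-0.23, adjusted p = 0.194), Aldh1l1 (0.10, 0.447), Slc1a2 (-0.22, 0.131), Vim (0.01, 0.929), Nes (0.48, 0.138), Aif1 (0.31, 0.335) and Prnp (-0.09, 0.565) did not pass. With the most variable probe set Nes (0.99, adjusted p = 0.000602) and Slc1a2 (-0.50, 0.0209) passed, and Nes passed with only the 6 arrays compared (0.0253).

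In all, 5724 probe sets passed in adult cells, 2580 higher and 3144 lower, from 1503 higher and 1710 lower genes. The count was 3622 without adult wild-type replicate 2, 3213 over genes in place of probe sets and 3360 with at least a 1.5-fold change as well. Of the 15 called lists, the 12 described kept their call in every fit that left out 1 array. Measures of other kinds were also compared between the 2 adult groups. The difference of the centred actin probe sets, 5′ end minus 3′ end, was at -0.27 on APdE9 relative to wild-type sections, with an exact permutation p of 0.1, two-sided, the smallest that 3 against 3 arrays allow. That of the Gapdh control probe sets was at -0.11 (exact permutation p = 0.1). The mean of the adult wild-type arrays was 0.221 for actin, against -0.0841 to -0.0125 in the other groups. It was 0.0836 for Gapdh, against -0.133 to -0.0133. These arrays also enter age on wild-type sections and the difference of section effects. What the shift adds to these comparisons was not tested. Xist, expressed from the inactive X chromosome of female cells, was higher on APdE9 sections by 1.06 (limma adjusted p = 0.000237; probe sets from 0.12 to 1.76), and the Y-linked gene Kdm5d was lower by -0.37 (adjusted p = 0.0314; probe sets from -1.14 to 0.10). Kdm5d lost its call without adult wild-type replicate 1 (0.0622), 2 (0.0982) or 3 (0.0765) and without adult APdE9 replicate 1 (0.0768) or 2 (0.128), with quantile normalization (0.103) and with the 8 arrays numbered 1 and 2 (0.084). The Y-linked genes Uty (-0.34, adjusted p = 0.0837) and Eif2s3y (-0.32, adjusted p = 0.109) did not pass, although Uty did with array weights (0.0481) and without adult wild-type replicate 3 (0.0482).

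**Figure D2:**
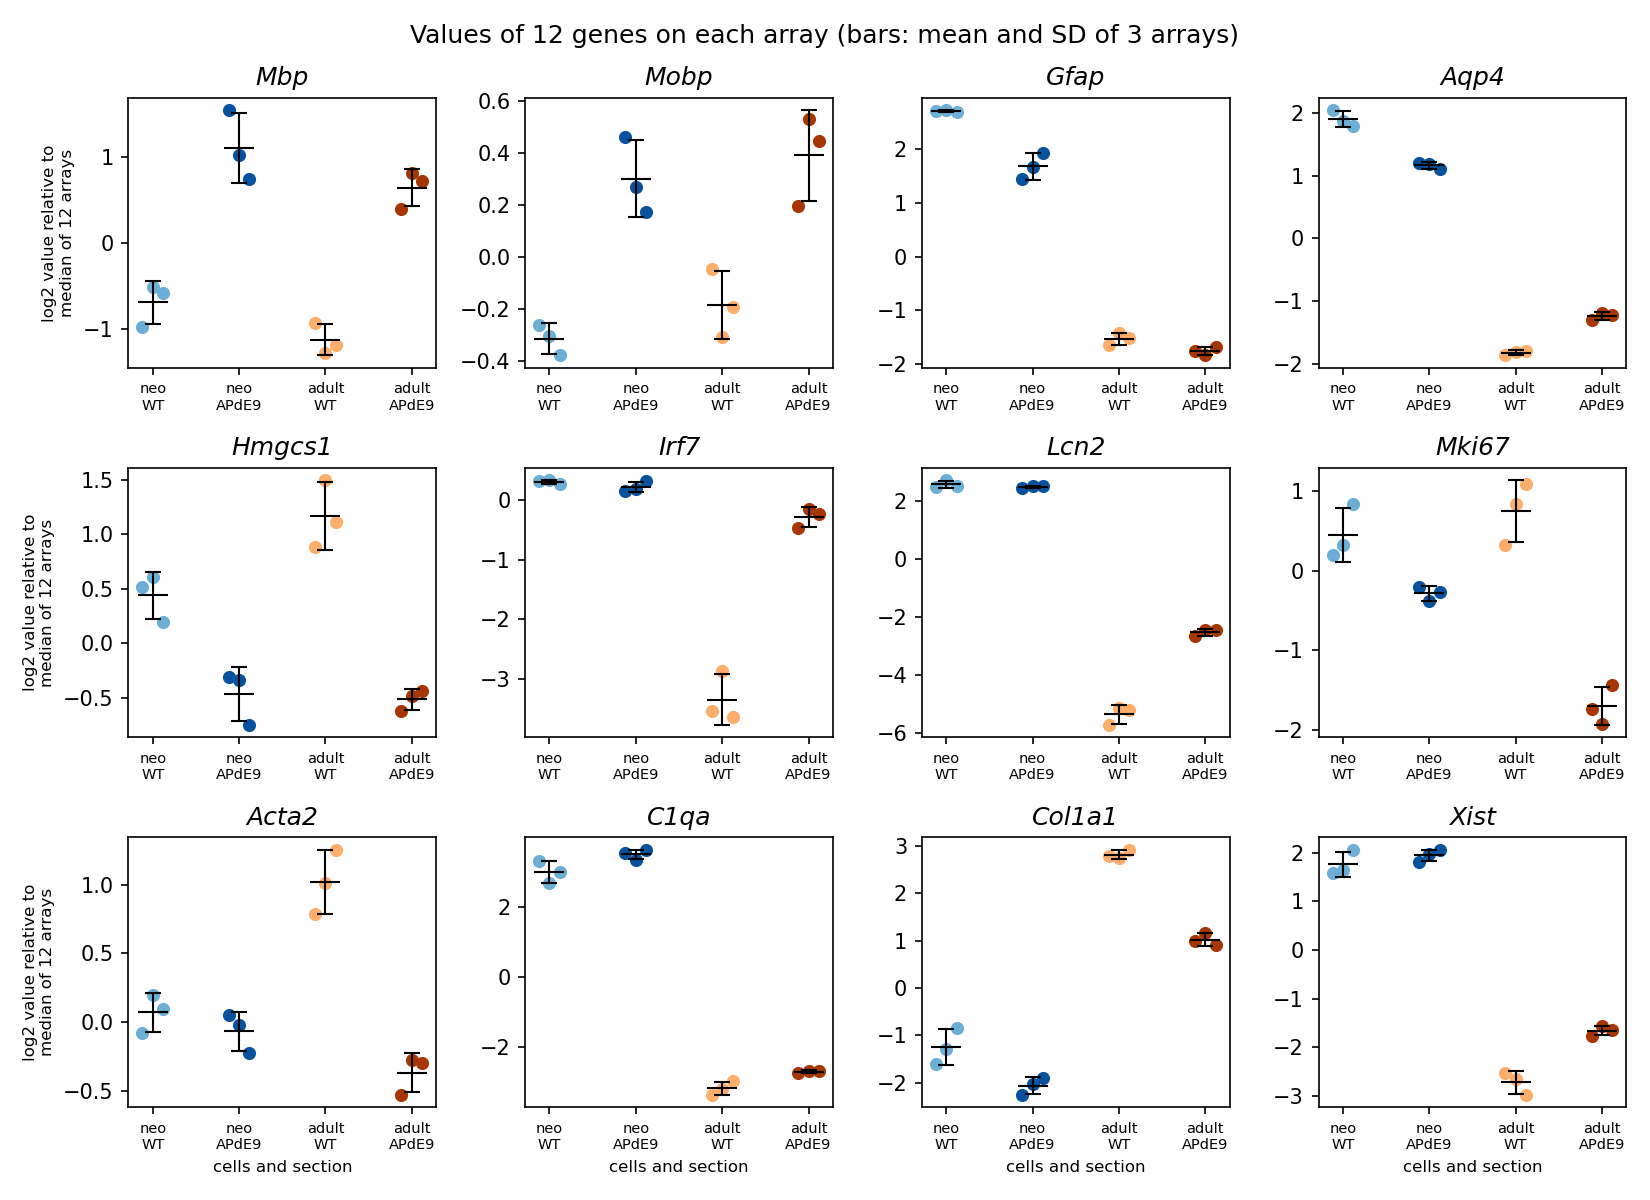
Each panel shows 1 of 12 named genes, with the log2 signal relative to the gene's centre over the 12 arrays on the vertical axis and the 4 groups of age and section on the horizontal axis; points are arrays and bars the group mean ± SD (n = 3). Irf7 and Lcn2 are higher on APdE9 sections in adult cells (3.06 and 2.83), Gfap is lower on them in neonatal cells (-1.02), and Hmgcs1 and Mki67 are lower on them in adult cells (-1.68 and -2.46).

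The third comparison tested whether the effect of the section differed between adult and neonatal astrocytes, as the difference of their log2 differences. The section effect on astrocyte markers was more positive in adult cells for 10 of 19 genes and more negative for none. For Apoe the section effects differed by 2.18 ± 0.13 (SE of the limma fit; adjusted p = 2.62e-06), for Acsbg1, an acyl-CoA synthetase, by 1.46 ± 0.19 (adjusted p = 0.00052), for Aldoc by 1.39 ± 0.11 (adjusted p = 1.65e-05) and for Aqp4 by 1.32 ± 0.11 (adjusted p = 2.66e-05). Aqp4 thus fell on APdE9 sections in neonatal cells and rose on them in adult cells. Of 26 interferon response genes 10 differed, all more positive in adult cells, led by Irf7 (3.14 ± 0.24, adjusted p = 1.04e-05) and Bst2 (1.88 ± 0.26, adjusted p = 0.00081). Of 31 cell cycle genes 8 differed, all more negative in adult cells, led by the ribonucleotide reductase gene Rrm2 (-2.16 ± 0.24, adjusted p = 0.000192) and the cyclin gene Ccne2 (-1.96 ± 0.37, adjusted p = 0.00572). Over the list alone the counts were 10 higher and 1 lower for astrocyte markers, 14 higher for interferon genes and 13 lower for cell cycle genes. The camera adjusted p was 2.75e-05 for astrocyte markers (adjusted p = 0.122 with an estimated correlation), 3.59e-06 for interferon genes (adjusted p = 0.504 with an estimated correlation) and 2.95e-10 for cell cycle genes (adjusted p = 0.504 with an estimated correlation). The untested share of microglia in the cells limits these differences too.

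Smaller differences of the section effect were seen in 5 further lists. Lipid transport genes were more positive in adult cells for 6 of 14, with Apoe first and Lcat, which esterifies cholesterol, next (1.24 ± 0.14), and for 8 over the list alone (limma camera adjusted p = 0.000211; adjusted p = 0.122 with an estimated correlation). Oxidative stress genes were more positive for 6 of 17 and more negative for 1, led by Gsta4 (2.00 ± 0.17) and Gclm (1.74 ± 0.16), with 7 and 2 over the list alone (0.00851; adjusted p = 0.122 with an estimated correlation). Antigen presentation genes were more positive for 3 of 17, led by H2-K1 (1.41 ± 0.11) and H2-D1 (0.70 ± 0.10), with 4 over the list alone (0.0111; adjusted p = 0.122 with an estimated correlation, and 0.101 with quantile normalization). Unfolded protein response genes were more negative for 3 of 23, led by Asns (-1.64 ± 0.16) and the pseudokinase gene Trib3 (-1.44 ± 0.13), with 4 over the list alone (0.000635; adjusted p = 0.266 with an estimated correlation). Glycolysis and hypoxia genes were more negative for 5 of 22, led by Adm (-2.23 ± 0.35), and more positive for 1, Aldoc, with 6 and 2 over the list alone (0.000635; adjusted p = 0.54 with an estimated correlation, and 0.135 with the directional fry test). These 8 of the 11 called lists kept their call in each fit that left out 1 array.

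The genes with the most positive difference of section effects were Ccl5 (4.61 ± 0.11), Mmp13 (3.54 ± 0.68), Ctss (3.25 ± 0.31), Irf7, Pou2af1 (3.10 ± 0.21), Aldh3a1 (3.04 ± 0.16), Lcn2 (2.91 ± 0.19), Ifi207 (2.54 ± 0.63), the glutathione transferase gene Gsta2 (2.46 ± 0.18) and the complement factor gene Cfb (2.45 ± 0.20). Those with the most negative difference were Ppbp (-6.10 ± 0.32), Cxcl5 (-4.90 ± 0.27), Ms4a4d (-3.39 ± 0.36), Cavin2 (-2.96 ± 0.19), Tagln (-2.89 ± 0.21), Actg2 (-2.87 ± 0.29), Lrrc15 (-2.78 ± 0.18), Filip1l (-2.68 ± 0.18), the microfibril gene Mfap5 (-2.48 ± 0.13) and Elobl (-2.43 ± 0.29). The limma adjusted p of these 20 genes lay between 4.67e-10 and 0.025, the highest being that of Ifi207. Ifi207 lost its call without adult APdE9 replicate 1 (adjusted p = 0.0502) or 2 (0.0556), adult wild-type replicate 3 (0.0501), neonatal APdE9 replicate 2 (0.0595) or 3 (0.056) and neonatal wild-type replicate 1 (0.0534) or 2 (0.053), and with quantile normalization (0.0858).

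Of the fixed panel, Gfap (0.79 ± 0.16, limma adjusted p = 0.00812), Slc1a3 (0.67 ± 0.13, 0.00713) and Aldh1l1 (0.60 ± 0.11, 0.00612) had a more positive section effect in adult cells. With quantile normalization the adjusted p of Gfap was 0.0997 and that of Slc1a3 was 0.0756, and with the most variable probe set of each gene that of Gfap was 0.105 and that of Aldh1l1 was 0.055. Cd68 (0.89 ± 0.25, 0.0463) and Clu (0.54 ± 0.14, 0.0316) passed too, but with quantile normalization they were at 0.40 (adjusted p = 0.229) and 0.21 (0.524). Cd68 also missed the threshold with median centring (0.0518) and Clu with its most variable probe set (0.0824). With the 8 arrays numbered 1 and 2 the adjusted p was 0.0585 for Cd68, 0.0631 for Clu, 0.0684 for Slc1a3 and 0.095 for Aldh1l1. Clu lost its call without adult APdE9 replicate 1 (0.0585) or 2 (0.0808), adult wild-type replicate 1 (0.0615), neonatal APdE9 replicate 1 (0.0508), 2 (0.0547) or 3 (0.0685) and neonatal wild-type replicate 2 (0.0848). Cd68 lost its call without adult APdE9 replicate 1 (0.0736), 2 (0.108) or 3 (0.0638), adult wild-type replicate 2 (0.0808) or 3 (0.0838), neonatal APdE9 replicate 1 (0.0844), 2 (0.0851) or 3 (0.0794) and neonatal wild-type replicate 1 (0.0741) or 2 (0.076). S100b, Slc1a2, Gja1, Vim, Nes, Aif1, App and Prnp did not pass, with adjusted p between 0.2 and 0.817. With the most variable probe set Nes (1.17, adjusted p = 0.00449), App (-0.88, 0.0345) and S100b (0.56, 0.0374) passed, from gene means of 0.31, -0.22 and 0.37. In all, 3029 probe sets had a section effect that differed with age, 1514 more positive and 1515 more negative in adult cells. With the 8 arrays numbered 1 and 2 they were 598 and 1128. The count was 1905 without neonatal wild-type replicate 2, 1965 without adult wild-type replicate 2, 1831 over genes and 4805 with array weights.

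Averaged over both ages, cholesterol biosynthesis genes fell on APdE9 sections in 19 of 19 cases, led by Idi1 (log2 difference -1.48 ± 0.18, limma adjusted p = 0.000172) and Hmgcs1 (-1.29 ± 0.12, adjusted p = 2.09e-05). Cell cycle genes fell in 22 of 31 cases, led by Mki67 (-1.60 ± 0.14, adjusted p = 1.92e-05) and the ubiquitin-conjugating enzyme gene Ube2c (-1.51 ± 0.18, adjusted p = 0.000141). Interferon response genes rose in 22 of 26, led by Irf7 (1.48 ± 0.12, adjusted p = 8.45e-06) and Rsad2 (1.45 ± 0.22, adjusted p = 0.000883), both antiviral. Microglia markers rose in 11 of 21 and fell in 1, led by Ctss (1.91 ± 0.16, adjusted p = 1.03e-05) and Cd68 (1.27 ± 0.13, adjusted p = 4.41e-05). Plaque-associated microglia genes rose in 7 of 18 and fell in 1, led by Cst7 (0.95 ± 0.14) and Gpnmb (0.91 ± 0.11). Matrix remodelling genes rose in 8 of 19 and fell in 2, led by the proteases Mmp13 (2.52 ± 0.34) and Mmp12 (1.97 ± 0.09). Adjusted over the list alone, the counts were 19 lower, 24 lower, 23 higher, 13 higher and 1 lower, 10 higher and 2 lower, and 8 higher and 2 lower, in the same order. The camera adjusted p, with that at an estimated correlation in brackets, was 1.88e-23 (adjusted p = 0.0876 with an estimated correlation) for cholesterol synthesis, 7.14e-19 (0.187) for cell cycle, 2.73e-17 (0.165) for interferon, 9.56e-07 (0.187) for microglia, 0.000195 (0.209) for the plaque-associated list and 0.00694 (0.165) for matrix remodelling.

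Of the 17 lists called over both ages, 15 kept their call in each fit that left out 1 array, and antigen presentation was the one also called with an estimated correlation (adjusted p = 0.039 there, 9.09e-06 with the preset one), with 7 of 17 genes higher and 8 over the list alone. Of the 8 lists not yet given, extracellular matrix genes fell in 16 of 30 cases and rose in 2, astrocyte markers fell in 8 of 19 and rose in 3, immediate early genes fell in 8 of 23 and glutamate and ion homeostasis genes in 4 of 15. Lipid transport genes rose in 5 of 14, lysosome genes in 5 of 20, oxidative stress genes in 4 of 17 with 1 lower, and the A1-type reactive set in 5 of 9 with 1 lower. In this order the camera adjusted p was 1.46e-06 (adjusted p = 0.187 with an estimated correlation), 0.00231 (0.165), 1.94e-06 (0.328), 0.00286 (0.305), 0.00694 (0.165), 0.00286 (0.219), 0.00423 (0.152) and 0.0132 (0.165). Over the list alone the counts were 16 lower and 3 higher, 10 lower and 3 higher, 11 lower, 6 lower, 6 higher, 7 higher, 6 higher and 1 lower, and 6 higher and 2 lower. Further genes among the 10 largest rises over both ages were Ccl5 (2.66 ± 0.06), Ifi207 (2.06 ± 0.32), Saa3 (2.00 ± 0.18), Abcb1a (1.94 ± 0.15), Mbp (1.79 ± 0.14), Ifi204 (1.65 ± 0.20) and the macrophage pore-forming gene Mpeg1 (1.59 ± 0.10). The 10 largest falls were Ppbp (-2.61 ± 0.16), Elobl (-2.59 ± 0.15), Cavin2 (-2.20 ± 0.09), Actg2 (-2.17 ± 0.15), Myl9 (-2.10 ± 0.10), Cnn1 (-2.01 ± 0.27), Cxcl5 (-1.98 ± 0.14), Depdc1a (-1.96 ± 0.22), Tagln (-1.92 ± 0.10) and Serpinb1a (-1.71 ± 0.12). A mean over ages can rest on the adult cells. The section effects of Ppbp, Cxcl5 and Irf7 differed between the ages by -6.10, -4.90 and 3.14. In neonatal cells the effect on each had the opposite sign to its mean. Apoe was at -0.26 in neonatal and 1.92 in adult cells. Of the fixed panel Apoe (0.83 ± 0.07, limma adjusted p = 8.61e-06), S100b (0.42 ± 0.08, 0.00446) and Aif1 (0.59 ± 0.14, 0.0159) rose and Gfap (-0.63 ± 0.08, 0.000246) and Gja1 (-0.44 ± 0.06, 0.000422) fell. With quantile normalization the adjusted p of Aif1 was 0.0529, and with the 8 arrays numbered 1 and 2 it was 0.116. With the most variable probe set Nes (0.41, adjusted p = 0.0223) and Slc1a2 (-0.38, 0.018) passed.

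Between the ages the section effects were weakly related across the 45037 probe sets, which are not independent replicates (Pearson r = 0.156, Spearman rho = 0.0463), and no array is shared between them. Without neonatal wild-type replicate 3 the Pearson r was 0.0803, and with the 8 arrays numbered 1 and 2 it was 0.0675. Among probe sets called at either age r was 0.248. There were 90 probe sets higher at both ages, where independent lists would share 15.0, and 209 lower at both ages, against 44.6. Those called in opposite directions were 27 higher in neonatal and lower in adult cells, against 18.3, and 70 lower in neonatal and higher in adult cells, against 36.6. The counts were compared without a p-value. Both calls of a probe set used the same estimate of its spread, so probe sets with a small estimate pass more easily at both ages. The numbers for independent lists can therefore be too low. The excess of shared calls does not by itself show a shared response. Averaged over both ages 3722 probe sets passed limma's test with Benjamini-Hochberg adjustment, 1458 higher and 2264 lower, and 2339 genes did. The count was 1349 with at least a 1.5-fold change as well.

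**Figure D3:**
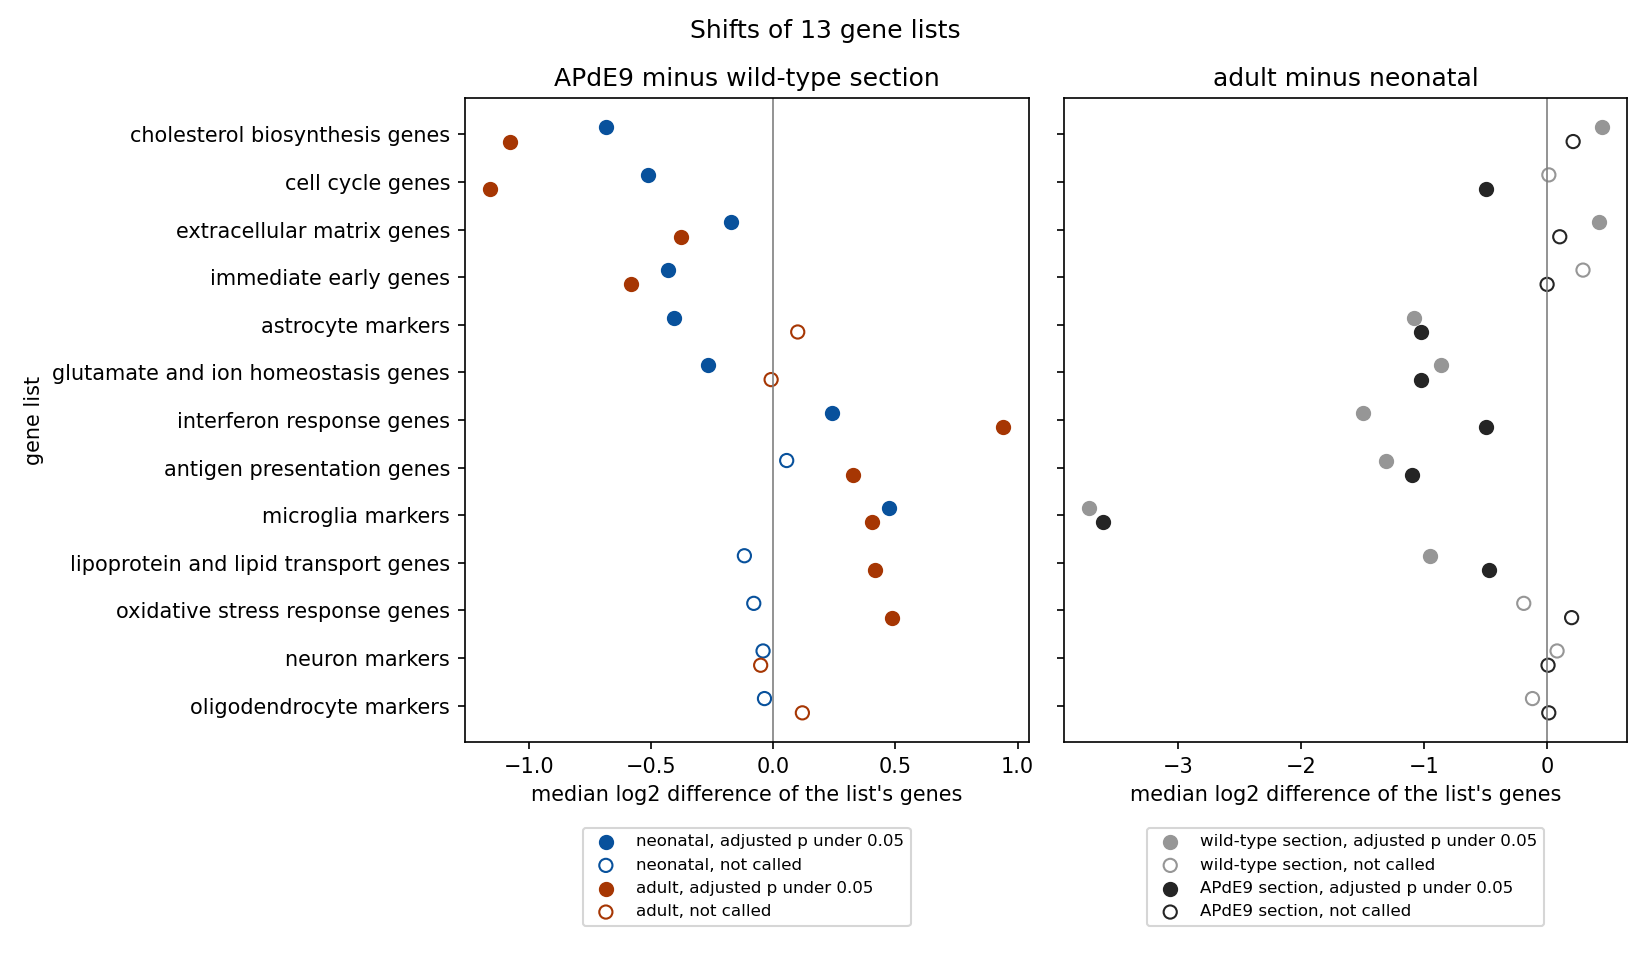
Points show the median log2 difference of the genes of 13 lists for APdE9 minus wild-type section in neonatal and adult cells (left) and for adult minus neonatal cells on each section (right), on horizontal axes of different range, filled where the camera adjusted p was under 0.05. Cholesterol and cell cycle genes lie below 0 on the left at both ages, interferon genes above 0 (0.24 in neonatal and 0.94 in adult cells), and microglia markers far below 0 on the right (-3.72 and -3.60).

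The fourth comparison set adult against neonatal astrocytes on wild-type sections; culture medium and isolation differed along with age, since only the adult cultures had Percoll separation and a G5 growth supplement. Microglia, complement and astrocyte genes were lower in adult cells. The arrays do not tell lower levels of microglia and immune genes in astrocytes from a smaller share of microglia in the adult cultures. That share was not tested. Microglia markers fell in 18 of 21 cases and rose in 1. Ctss was at a log2 difference of -7.60 ± 0.22 (SE of the limma fit, n = 3 arrays per group; adjusted p = 1.52e-10), and the complement genes C1qc, C1qb and C1qa, of the first component of the classical pathway, at -7.02 ± 0.21, -6.78 ± 0.31 and -6.20 ± 0.14 (adjusted p up to 6.41e-09). Of 14 complement genes 11 fell and 2 rose, with C3ar1, the receptor of the C3a fragment, at -4.62 ± 0.23. The counts over the list alone were the same for both lists. Astrocyte markers fell in 16 of 19 cases and rose in 2, or 3 over the list alone, with Aldoc at -4.97 ± 0.08 (adjusted p = 1.5e-12), Gfap at -4.24 ± 0.11 (adjusted p = 7.05e-11) and Aqp4 at -3.73 ± 0.08 (adjusted p = 1.25e-11). The camera adjusted p was 1.65e-15 for microglia markers (adjusted p = 0.0401 with an estimated correlation), 1.22e-07 for complement genes (0.00569) and 2.78e-12 for astrocyte markers (0.00569).

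Antigen presentation genes fell in 15 of 17 cases and rose in 1 in adult cells on wild-type sections, led by the costimulatory gene Cd86 (-2.96 ± 0.30) and by H2-K1 (-2.51 ± 0.08), with the same counts over the list alone (limma camera adjusted p = 2.63e-10; adjusted p = 0.00438 with an estimated correlation). Interferon response genes fell in 22 of 26, or 23 over the list alone, led by Irf7 (-3.64 ± 0.17) and the chemokine gene Cxcl10 (-3.38 ± 0.73) (4.86e-14; adjusted p = 0.124 with an estimated correlation). Of 31 chemokine and cytokine genes 16 fell and 3 rose, with 16 and 4 over the list alone (0.00148; adjusted p = 0.36 with an estimated correlation). Ccl3 was at -6.72 ± 0.45 and Ccl5 at -6.09 ± 0.08, and Cxcl5 was at 6.20 ± 0.19. Of 19 NF-kB target genes 8 fell and 1 rose, with 9 and 2 over the list alone, led by Lcn2 (-7.91 ± 0.14) and the receptor gene Tlr2 (-4.86 ± 0.51) (0.00172; adjusted p = 0.54 with an estimated correlation). Of 19 amyloid and scavenger receptor genes 11 fell and 5 rose, with 12 and 5 over the list alone, led by Cd36 (-4.89 ± 0.21, probe sets from -6.58 to -2.60) and Tlr2 (0.00108; adjusted p = 0.0401 with an estimated correlation). Plaque-associated microglia genes fell in 13 of 18 and rose in 2, or 3 over the list alone, led by the adaptor gene Tyrobp (-5.35 ± 0.19) and the chemokine gene Ccl6 (-4.82 ± 0.10) (2.7e-08; adjusted p = 0.0689 with an estimated correlation).

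Glial function lists were also called in adult cells on wild-type sections. Lipid transport genes fell in 10 of 14 cases, the same over the list alone, led by the chaperone gene Clu (-4.37 ± 0.10) and the lipase gene Lpl (-4.11 ± 0.18) (limma camera adjusted p = 5.86e-08; adjusted p = 0.012 with an estimated correlation). Glutamate and ion homeostasis genes fell in 10 of 15 and rose in 1, or 2 over the list alone, with Aqp4 first and Slc1a3 at -3.22 ± 0.09 (1.22e-07; adjusted p = 0.0751 with an estimated correlation). Radial glia and progenitor genes fell in 9 of 16, or 10 over the list alone, led by the Notch target gene Hes5 (-3.97 ± 0.55, probe sets from -5.64 to -2.30) and Prom1 (-3.53 ± 0.13) (4.41e-06; adjusted p = 0.051 with an estimated correlation). Ependymal and choroid plexus markers fell in 8 of 12, the same over the list alone, led by transthyretin, Ttr (-2.15 ± 0.51), and the dynein gene Dynlrb2 (-1.78 ± 0.17) (0.000338; adjusted p = 0.131 with an estimated correlation). Of 13 pan-reactive genes 7 fell and 2 rose, or 3 over the list alone, led by Lcn2 and Gfap (0.00719; adjusted p = 0.171 with an estimated correlation). Of 9 genes of the A1-type reactive set 7 fell and 1 rose, with the same counts over the list alone, led by Srgn (-5.25 ± 0.19) and Psmb8 (-1.79 ± 0.13) (0.000267; adjusted p = 0.0401 with an estimated correlation).

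The lists called upward in adult cells on wild-type sections included matrix, unfolded protein response and cholesterol genes. Of 30 extracellular matrix genes 14 rose and 3 fell, with 16 and 3 over the list alone (limma camera adjusted p = 0.000951; adjusted p = 0.36 with an estimated correlation). Col1a1 was at 4.06 ± 0.16 (adjusted p = 2.02e-09), and the brain proteoglycan genes Ncan and Bcan were among those lower, at -3.75 ± 0.08 and -3.62 ± 0.10. Unfolded protein response genes rose in 10 of 23 cases, or 11 over the list alone, led by Asns (1.72 ± 0.11) and Trib3 (1.42 ± 0.09) (0.000526; adjusted p = 0.127 with an estimated correlation). Cholesterol biosynthesis genes rose in 12 of 19, or 13 over the list alone, led by the sterol enzymes Msmo1 (0.87 ± 0.25, adjusted p = 0.0191) and Nsdhl (0.82 ± 0.15, adjusted p = 0.00138) (0.000826; adjusted p = 0.448 with an estimated correlation). Msmo1 lost its call without neonatal wild-type replicate 3 (adjusted p = 0.0726) and without adult wild-type replicate 2 (adjusted p = 0.0713).

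The 10 genes with the largest rise on wild-type sections were Brinp3 (7.11 ± 0.16), Cxcl5, Abi3bp (4.76 ± 0.18), Crct1 (4.50 ± 0.61), Cavin2 (4.36 ± 0.13), Fndc3c1 (4.36 ± 0.18), the growth factor binding gene Igfbp6 (4.30 ± 0.17), the prostacyclin synthase gene Ptgis (4.28 ± 0.16), the retinoid-binding gene Crabp2 (4.27 ± 0.17) and Mfap5 (4.27 ± 0.09). The largest falls, beyond those given, were the macrophage genes Lyz2 (-6.94 ± 0.15), Clec4d (-5.95 ± 0.15) and Adgre1 (-5.94 ± 0.26). The limma adjusted p of these 13 genes was at most 0.000106. Of the fixed panel Apoe (-3.55 ± 0.09), Aif1 (-4.52 ± 0.20) and Cd68 (-4.49 ± 0.18) fell, as did Slc1a2 (-0.57 ± 0.09), Aldh1l1 (-0.53 ± 0.08) and Prnp (-0.36 ± 0.09), and S100b (0.58 ± 0.12) and Gja1 (0.35 ± 0.09) rose, with adjusted p at most 0.00984. The 6 probe sets of Slc1a3 ranged from -5.22 to -0.92 and those of Slc1a2 from -1.57 to 0.12, and Prnp did not pass with its most variable probe set (adjusted p = 0.128). Nes (-0.58, adjusted p = 0.0517), App (0.17, 0.158) and Vim (-0.03, 0.83) did not pass. With the most variable probe set Nes (-1.43, adjusted p = 1.07e-05) and App (0.61, 0.0151) passed. Nes also passed with array weights (0.00841), median centring (0.0445), only the 6 arrays compared (0.0211), the 8 arrays numbered 1 and 2 (0.0304) and the replicate number as a block (0.0164). In all, 10331 probe sets passed, 5485 higher and 4846 lower in adult cells, or 4364 higher and 4910 lower with quantile normalization, from 2718 higher and 2764 lower genes. The count over genes was 5482, and 6595 with at least a 1.5-fold change as well. Of 20 called lists, the 18 described kept their call in each fit that left out 1 array. Xist was lower in adult cells by -4.48 and the median of 3 Y-linked genes higher by 1.42. The 5′ end to 3′ end difference was higher in adult cells by 0.23 for actin and by 0.22 for Gapdh (exact permutation p = 0.1 for each, two-sided, the smallest possible).

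The fifth comparison set adult against neonatal astrocytes on APdE9 sections, with the same difference of medium and isolation and the same limit on microglia and immune genes. Microglia markers fell in 18 of 21 cases with none higher. C1qb was at -7.07 ± 0.31 (SE of the limma fit, n = 3 arrays per group; adjusted p = 6.75e-09), C1qc at -6.48 ± 0.21 (8.94e-10) and C1qa at -6.23 ± 0.14 (6.9e-11), and Aif1 at -5.08 ± 0.20 (2.67e-09). Of 14 complement genes 11 fell and 2 rose, with C3ar1 at -4.66 ± 0.23. Astrocyte markers fell in 13 of 19 cases and rose in 1, with 14 and 1 over the list alone, led by Aldoc (-3.59 ± 0.08) and Gfap (-3.45 ± 0.11). Glutamate and ion homeostasis genes fell in 9 of 15, led by Slc1a3 (-2.55 ± 0.09) and Aqp4 (-2.40 ± 0.08). The counts over the list alone were the same for microglia markers, complement and glutamate genes. Camera gave an adjusted p of 2.24e-21 for microglia markers (adjusted p = 0.0191 with an estimated correlation), 9.64e-09 for complement (0.00453), 1.29e-11 for astrocyte markers (0.00654) and 2.56e-08 for glutamate and ion homeostasis (0.0539).

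Other immune lists were called in adult cells on APdE9 sections as well. Antigen presentation genes fell in 13 of 17 cases and rose in 1, the same over the list alone, led by Cd86 (-3.79 ± 0.30) and the class II gene H2-Aa (-1.96 ± 0.10) (limma camera adjusted p = 6.62e-09; adjusted p = 0.00453 with an estimated correlation). Plaque-associated genes fell in 10 of 18 and rose in 1, the same over the list alone, led by Ccl6 (-5.98 ± 0.10) and Tyrobp (-4.99 ± 0.19) (6.62e-09; adjusted p = 0.0539 with an estimated correlation). Interferon response genes fell in 13 of 26, the same over the list alone, led by Mx1 (-2.79 ± 0.26) and Cxcl10 (-2.51 ± 0.73) (4.64e-07; adjusted p = 0.289 with an estimated correlation). Chemokine and cytokine genes fell in 14 of 31 and rose in 3, with 15 and 5 over the list alone, led by Ccl3 (-5.85 ± 0.45) and Cxcl2 (-5.01 ± 0.81) (0.000883; adjusted p = 0.311 with an estimated correlation). NF-kB target genes fell in 9 of 19 and rose in 1, with 10 and 1 over the list alone, led by Lcn2 (-5.00 ± 0.14) and Tlr2 (-4.72 ± 0.51) (1.04e-05; adjusted p = 0.311 with an estimated correlation). Amyloid and scavenger receptor genes fell in 9 of 19 and rose in 4, with 10 and 4 over the list alone, led by Cd36 (-5.18 ± 0.21) and Tlr2 (6.05e-05; adjusted p = 0.0191 with an estimated correlation). Cxcl10 lost its call without adult APdE9 replicate 2 (adjusted p = 0.0819) or 3 (0.0768) and without neonatal APdE9 replicate 1 (0.0931) or 2 (0.0514).

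Lists that moved on APdE9 sections included cell cycle and glycolysis genes, which were not called between the ages on wild-type sections. Cell cycle genes fell in 17 of 31 cases, or 20 over the list alone, led by Mki67 (-1.42 ± 0.20) and Rrm2 (-1.40 ± 0.17) (limma camera adjusted p = 1.38e-07; adjusted p = 0.329 with an estimated correlation). Glycolysis and hypoxia genes fell in 10 of 22 and rose in 1, with 12 and 1 over the list alone, led by Aldoc and Adm (-1.44 ± 0.25) (1.04e-05; adjusted p = 0.273 with an estimated correlation). Lipid transport genes fell in 8 of 14 and rose in 2, the same over the list alone, led by Lpl (-3.86 ± 0.18) and Clu (-3.83 ± 0.10) (3.47e-05; adjusted p = 0.0328 with an estimated correlation). Radial glia genes fell in 9 of 16 and rose in 1, with 11 and 1 over the list alone, led by Prom1 (-3.18 ± 0.13) and Tnc (-2.91 ± 0.40) (1.04e-05; adjusted p = 0.0539 with an estimated correlation). Pan-reactive genes fell in 7 of 13 and rose in 1, with 7 and 2 over the list alone, led by Lcn2 and Gfap (5.62e-05; adjusted p = 0.0539 with an estimated correlation). The A1-type reactive set fell in 7 of 9 and rose in 1, with 8 and 1 over the list alone, led by Srgn (-5.16 ± 0.19) and Psmb8 (-1.59 ± 0.13) (2.49e-06; adjusted p = 0.0159 with an estimated correlation). Ependymal markers fell in 6 of 12, or 8 over the list alone, led by Dynlrb2 (-1.11 ± 0.17) and Foxj1 (-0.98 ± 0.14) (0.00192; adjusted p = 0.21 with an estimated correlation). Ribosomal protein genes rose in 7 of 16, or 12 over the list alone, among them Rpl13a (0.38 ± 0.08) (0.00172; adjusted p = 0.329 with an estimated correlation).

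The 10 genes with the largest rise on APdE9 sections were Fndc3c1 (4.91 ± 0.18), the cartilage proteoglycan gene Epyc (4.88 ± 0.20), Igfbp6 (4.81 ± 0.17), Brinp3 (4.79 ± 0.16), Ptgis (4.71 ± 0.16), Prss12 (4.41 ± 0.12), Perp (4.13 ± 0.14), Dmkn (4.12 ± 0.21), Akr1c18 (4.06 ± 0.23) and Esam (3.87 ± 0.15). The largest falls, beyond those given, were Slc15a3 (-5.94 ± 0.23), Adgre1 (-5.85 ± 0.26), Lyz2 (-5.84 ± 0.15), Gatm (-5.72 ± 0.20) and Glycam1 (-5.64 ± 0.20). The limma adjusted p of these 15 genes was at most 5.55e-08. Of the fixed panel Cd68 (-3.60 ± 0.18), Apoe (-1.37 ± 0.09) and Slc1a2 (-0.73 ± 0.09) fell and S100b (0.95 ± 0.12) rose, with adjusted p at most 7.08e-05, and Aldh1l1, Gja1, Vim, Nes, App and Prnp did not pass (adjusted p between 0.397 and 0.845). In all, 7401 probe sets passed, 3623 higher and 3778 lower in adult cells, from 2121 higher and 2158 lower genes. The count was 4279 over genes and 4568 with at least a 1.5-fold change as well. Of 21 called lists, the 18 described kept their call in each fit that left out 1 array. Xist was lower in adult cells by -3.60 and the median of 3 Y-linked genes higher by 1.04. The 5′ end to 3′ end difference was at 0.038 for actin and -0.016 for Gapdh (exact permutation p = 0.5 and 0.9, two-sided).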

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

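The tests of carried-over microglia and neuron RNA were chosen only after the result was seen, as was the look at the splits that kept the adult arrays; the counts of other splits were chosen before. The results below differed between the ages: the effect of the section in adult astrocytes minus that in neonatal astrocytes passed a test of the difference itself. There were 3029 such probe sets. In 1 of 100 drawn splits of the 12 arrays within each age, of 200 possible, as many were called, the real one, and the highest other split called 2761. Most of these splits also mix the adult groups, so they test for no section effect at either age and not for an equal effect at both. The 11 other drawn splits that kept the adult arrays in their real groups, or mirrored them, called 1185 to 2761, and they are too few for a share under 0.05. The count was 1905 without neonatal wild-type replicate 2 and 1965 without adult wild-type replicate 2.

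By gene list, the median difference of section effects was 0.60 for astrocyte markers, 0.32 for radial glia and progenitor genes, 0.44 for lipid transport genes (0.435), 0.83 for interferon response genes, 0.19 for antigen presentation genes (0.195) and 0.43 for oxidative stress genes. It was -0.65 for cell cycle genes, -0.22 for unfolded protein response genes, -0.45 for glycolysis and hypoxia genes, -0.13 for extracellular matrix genes and -0.36 for immediate early genes. All 11 lists lost their call with an estimated correlation. Radial glia genes (adjusted p = 0.504 there) also lost it with quantile normalization (0.165), the most variable probe set (0.0852), the replicate number as a block (0.0654) and the 8 arrays numbered 1 and 2 (0.088). They lost it too without neonatal wild-type replicate 1 (0.0574) or 2 (0.063), neonatal APdE9 replicate 3 (0.143), adult wild-type replicate 2 (0.0535) or 3 (0.104) and adult APdE9 replicate 1 (0.101) or 2 (0.07). Extracellular matrix genes (0.636 with an estimated correlation) lost their call with fry (0.441), with quantile normalization (0.213) and without neonatal wild-type replicate 1 (0.0574) or 2 (0.0573) or neonatal APdE9 replicate 3 (0.115). Immediate early genes (0.796 with an estimated correlation) lost theirs with fry (0.472) and quantile normalization (0.165). They also lost it without neonatal wild-type replicate 3 (0.34), neonatal APdE9 replicate 1 (0.123) or 2 (0.127), adult wild-type replicate 1 (0.0576) or 2 (0.21) and adult APdE9 replicate 3 (0.253). Among single genes the difference was 4.61 for Ccl5, 3.54 for Mmp13, 3.25 for Ctss, 3.14 for Irf7, 3.10 for Pou2af1, 3.04 for Aldh3a1, 2.91 for Lcn2, 2.54 for Ifi207, 2.46 for Gsta2 and 2.45 for Cfb. It was -6.10 for Ppbp, -4.90 for Cxcl5, -3.39 for Ms4a4d, -2.96 for Cavin2, -2.89 for Tagln, -2.87 for Actg2, -2.78 for Lrrc15, -2.68 for Filip1l, -2.48 for Mfap5 and -2.43 for Elobl. In the fixed panel it was 2.18 for Apoe, 1.32 for Aqp4, 0.79 for Gfap, 0.89 for Cd68, 0.67 for Slc1a3, 0.60 for Aldh1l1 and 0.54 for Clu.

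Interferon response genes were higher on APdE9 sections in adult astrocytes, with a list median of 0.94 (95% bootstrap interval 0.594 to 1.55; camera adjusted p = 0.254 with an estimated correlation). Between the same groups Xist was at 1.06 and the centred 5′ minus 3′ difference at -0.27 for actin and -0.11 for Gapdh (exact permutation p = 0.1 for each, the smallest possible). Microglia carried over or multiplying in the culture stay open: 10 microglia markers had a median of 0.42 (0.422, interval 0.229 to 0.627), on either side of 0.470, which is the interferon median over 2, although cultures were shaken to remove microglia and fluorescent cells were picked from the section. With quantile normalization the median of the whole microglia list went from 0.40 to 0.12 and was not called (adjusted p = 0.151), and C1qc went from 1.01 to 0.12. In centred values the spread that this step equalizes holds group differences. The loss thus does not decide whether the rise was real. Tmem119 was lower (-0.85). RNA of section neurons stays open too: neuron markers had a median of -0.05 (-0.0518, interval -0.291 to 0.0558), but levels had been removed, so markers near the floor or high at baseline could hide a small share. A response of the astrocytes to the APdE9 section, which the design names, was not tested apart from these and also stays open.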

How the results depend on the processing

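Alternatives with the gene mean, the most variable probe set, the SD filter, robust variances, restored decimal points and the 8 arrays numbered 1 and 2 were chosen after the data were seen. No named gene that passed changed sign and no called list changed its camera direction, but the median of the chemokine and cytokine list in neonatal cells (0.14, called) was -0.02 with the 8 arrays numbered 1 and 2 and -0.10 without neonatal wild-type replicate 3, where it was not called. That list also lost its call with an estimated correlation (camera adjusted p = 0.48), with fry (0.17) and without neonatal APdE9 replicate 1 (camera adjusted p = 0.0941). Quantile normalization turned the balance of age on wild-type sections from 5485 higher and 4846 lower to 4364 and 4910. It acted on centred values, whose SD per array ran from 0.340 to 0.439, highest in adult cells on wild-type sections. Giving every array the same spread can remove real group differences. Calls lost with it thus do not settle whether those differences were real. Median centring, robust variances, the SD filter and restored decimal points kept each count of probe sets within 1.5 times. Other counts moved; the cause was not tested, except that fewer units were tested with genes, a stricter or looser threshold applied, or fewer arrays used. With array weights, where neonatal wild-type replicate 2 had a weight of 4.77 and the other arrays 0.597 to 1.43, the neonatal count was 2250 and that of the difference between ages 4805. The neonatal count was 294 with only the arrays compared. With the 8 arrays numbered 1 and 2 the counts were 231 (neonatal), 1726 (difference) and 2199 (mean of ages). At an adjusted p under 0.10 they were 1395 (neonatal) and 4546 (difference). With at least a 1.5-fold change they were 3360 (adult), 1349 (mean), 6595 (age on wild-type) and 4568 (age on APdE9). With the mean of each gene's probe sets they were 3213, 1831 (difference), 2339, 5482 and 4279, and with the most variable probe set 3449, 2361, 5778 and 4399 (no such move for the difference). Leaving out each array in turn gave 289 to 889 for neonatal cells (289 without neonatal wild-type replicate 2, 514 without its replicate 3, 485 and 516 without neonatal APdE9 replicates 1 and 2), 3622 to 5798 for adult cells (3622 without adult wild-type replicate 2) and 1905 to 2815 for the difference (1905 without neonatal wild-type replicate 2, 1965 without adult wild-type replicate 2). The number of called lists was 15, 15, 11, 17, 20 and 21 in the order neonatal, adult, difference, mean, age on wild-type and age on APdE9. With an estimated correlation it was 1, 0, 0, 1, 7 and 7, with fry 6 (neonatal), 30 (adult), 35 and 34 (age), and with quantile normalization 7 for the difference. Leaving out arrays gave 13 to 23 for neonatal cells (23 without neonatal wild-type replicate 1).

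Of 418 gene values named or weighed, 368 passed the threshold as reported. Quantile normalization ended the call of 16 and gave a call to 1, median centring ended 5 and gave 3, and the most variable probe set ended 8 and gave 9. The 8 arrays numbered 1 and 2 ended 38 and gave 2, fitting only the arrays compared ended 12 and gave 2, array weights ended 1 and gave 7, and robust variances ended 4. The median over a gene's probe sets differed from the mean by 0.2 or more for 36 values. Averaged over ages, Aldh1l1 (-0.20, limma adjusted p = 0.0388) and App (-0.19, 0.0466) each lost their call without 10 of the arrays taken in turn, with adjusted p up to 0.0899 and 0.113. With the replicate number as a block the counts were 1344, 7395, 4457, 4914, 12135 and 8944, each within 1.5 times, sharing 883, 5654, 3012, 3679, 10226 and 7307 with those reported, and 10 of 12 arrays correlated best with their own number. The block changed the calls of Slc1a3 (0.0286), Arc (0.013) and Nr4a1 (0.0102) in neonatal cells, App (0.0522) and Prnp (0.0386) averaged over ages and Nes (0.0164) for age on wild-type sections. It also changed those of 4 lists, pericyte markers in adult cells (0.0625), radial glia genes for the difference (0.0654) and ribosomal (0.0549) and synaptogenic genes (0.0542) for age on wild-type sections. It changed no other call among the gene values named or weighed and the called lists. The relation of the section effects (r = 0.156) ranged from 0.0803 to 0.191 on leaving out arrays and was 0.0675 with the 8 arrays. Without levels the planned highest-mean probe set, dim filter and variance trend were not run and signal over background is unknown.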

Other observations

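The tests of the myelin and age patterns below were chosen only after the result was seen; the counts of other splits were chosen before. The myelin genes Mbp (1.80 ± 0.20 in neonatal and 1.78 ± 0.20 in adult cells, limma SE) and Mobp (0.62 and 0.57) were higher on APdE9 sections at both ages. The 5 probe sets of Mobp disagreed, from -0.04 to 2.91 in neonatal and -0.16 to 2.60 in adult cells. In neonatal cells Mobp lost its call with the 8 arrays numbered 1 and 2 (0.65, limma adjusted p = 0.0793). A fault of a single Mbp probe set is argued against, since 5 of 8 Mbp probe sets were called higher averaged over ages. A fault of a single Mobp probe set stays open, since 1 of 5 was called. The other oligodendrocyte markers had a median of 0.0117 (95% bootstrap interval -0.0893 to 0.0722, 12 genes) and neuron markers one of -0.0310 (-0.203 to 0.0160, 19 genes). RNA carried over from section oligodendrocytes or from section neurons stays open with these values, although fluorescent cells were picked from the section, because levels had been removed and markers near the floor or high at baseline could hide a small share.

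Astrocyte markers were lower in adult than in neonatal cells on both sections, and the extracellular matrix list was higher on wild-type sections (adjusted p = 0.36 with an estimated correlation). On APdE9 sections the matrix list was not called, with 7 genes higher and 7 lower. More fibroblast-type cells in adult cultures may add to this and stay open: 9 fibroblast markers outside the matrix list had medians of 0.0436 on wild-type sections (interval -1.57 to 1.94) and 0.131 on APdE9 sections (-0.545 to 1.58), with members going both ways. Growth factors and hydrocortisone in the adult medium stay open as well, with medians of -0.0497 on wild-type and 0.0631 on APdE9 sections for the FGF and ERK response list and -0.00360 and -0.257 for the glucocorticoid response list. Camera called the glucocorticoid list lower on APdE9 sections (adjusted p = 0.0206, and 0.21 with an estimated correlation). It did not without adult APdE9 replicate 3 (0.0948), with quantile normalization (0.0675) or with the most variable probe set (0.0563). Xist was at -4.48 on wild-type and -3.60 on APdE9 sections, and the median of 3 Y-linked genes at 1.42 and 1.04. These opposite directions are those that a different share of male and female animals would give. Whether that share adds to the marker pattern was not tested and stays open. Age itself, which the design names, was not tested apart from medium and isolation.

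For comparisons of 3 against 3 arrays the 10 splits are too few for a share under 0.05. The real counts were 901 for section in neonatal cells, 5724 for section in adult cells, 10331 for age on wild-type sections and 7401 for age on APdE9 sections, each the 1 split of 10 with as many called, and the highest other splits called 1, 0, 0 and 1. In neonatal cells the other splits that parted all 3 pairs of replicate numbers, as the real one does, called at most 1, and those that parted 1 pair called 0. For the mean of the section effects, 3722 were called and 1 of 100 drawn splits, the real one, called as many. The highest other split called 2761, and in it the adult arrays kept their real groups, mirrored. Many other splits put both arrays of a replicate number in the same group, which the real split does not. Of the 12 arrays, 10 correlated best with their own number. The share under 0.05 therefore does not exclude chance with no section effect at either age.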
